A study of Mus musculus with 37 samples.

How the data were processed

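Gene expression was measured by RNA sequencing in mouse embryonic stem (ES) cells, in Neuro2a (N2a) cells and in sorted cells of the embryonic mouse cortex. The series held 37 samples, of which the 25 RNA libraries were analysed. The 12 chromatin immunoprecipitation, input and ATAC samples were not analysed here.

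Per the submitters' processing notes, the reads belong to the mouse genome build mm9, and TopHat2 2.0.8, SAMtools 0.1.19, HTSeq 0.5.4p1 and DESeq were used for the RNA libraries, with Picard 2.9.0 named for the cortex libraries only. The notes give no role or order for these tools. The DESeq version, the gene annotation, the strand setting of the counting and the treatment of reads with several positions are not given in the sources used here. Genes that share sequence with near-identical copies, or that overlap a gene on the other strand, are therefore uncertain. The series text names 2 Illumina sequencers without saying which library ran on which.

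The authors deposited 1 table per system with 21937 gene symbols in each, and the deposited values are a linear signal, namely read counts per gene divided by a size factor per library. This was checked on the values. In each of the 25 libraries 100% of the values up to 1000 reads were whole multiples of the value of 1 read, with a tolerance of 0.05 reads. One read was worth 0.824 to 1.17 in the ES cell table, 0.877 to 1.16 in the N2a table and 0.382 to 1.68 in the cortex table. Whole reads were recovered by dividing by that value. The tables were normalised separately, so tests were made within a table and levels are not compared between tables. Of 21727 Entrez identifiers in the tables, 21656 matched a RefSeq gene table of assembly GRCm38.p6, which was used only to find older symbols. The symbols are printed as deposited, and no coordinates are given because the builds differ.

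The recovered reads per library were 19050639 to 27408626 in the ES cell table, 15029553 to 20173036 in the N2a table and 321826 to 1389034 in the cortex table. Libraries were grouped by their titles. Replicates of a group were compared with a chi-square test of their reads over genes, and all pairs differed by more than sampling noise (chi-square per degree of freedom from 2.04 to 147), so each library was counted as 1 sample. Nothing in the labels says that replicates came from separate cultures, animals or litters, so the p-values measure the spread between these samples, which may be technical.

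The tests, the gene lists, the rule for naming genes and most of the alternatives were fixed before the data were examined. Values were transformed to log2(value + 1), and a fold change on that scale understates the change of genes with low values. Genes with a mean deposited value of at least 10 over the libraries of a table were tested with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment, and a gene is called changed at an adjusted p under 0.05. This left 14060 genes in the ES cells, 12455 in N2a cells and 7910 in the cortex. All 4 N2a groups shared 1 fit, because 3 of them have 2 libraries. This fit assumes the same spread in every group, while the day 5 libraries differed more among themselves than the other groups did. The recovered reads were also tested with the quasi-likelihood test of edgeR 4.0.16 and with DESeq2 1.42.0.

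A set of 29 gene lists (653 symbols, 634 found in the tables, 14 of these through the Entrez identifier) covered the cell cycle, neural and other cell types, pluripotency, stress responses and metabolic pathways. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each list call was repeated with an estimated correlation and with the rotation test fry. Members are counted over all genes tested and adjusted over the list alone. With an estimated correlation no list passed in any comparison, and the adjusted p so obtained is given beside each call of the main fits. This held even for lists of which every tested member was called, namely G1/S and G2/M at day 2 in N2a cells. A call lost by this setting therefore does not show that a list was unchanged.

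Genes named in the text are Phf21b, its paralog Phf21a, up to 8 genes with the largest rise and 8 with the largest fall among called genes with no overlap of the groups and a mean of at least 50 in the higher group, and up to 4 members of each list with the smallest p. Symbols of the Gm and Rik forms, of ribosomal proteins and of small RNA families starting with Mir or Snor were left out by that rule. For the ES cells the rule was applied within pairs as well.

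Groups that share replicate numbers were checked for pairing by correlating the deviations of libraries from their group means. In the ES cells the same-numbered libraries correlated at 0.77 to 0.92 in all 5 pairs, and the first principal component (68.3% of the variance) separated replicates 1 and 2 from 3 to 5. The ES cell libraries were therefore also fitted within pairs. The replicate numbers of the N2a and cortex libraries did not pair them.

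Alternatives covered the pseudocount, the filter on low values, the scaling, the trend, the 2 count tests, a fold change minimum, the block on replicate numbers, the groups in the fit, the list test and each library left out in turn. Where this left a group with 1 library, that library was assumed to vary like the other groups. Comparisons that share libraries were set beside 100 simulated draws with no effect. The scripts were tested on simulated data drawn from the means and library sizes of each table, with a random set of genes changed by known amounts. Among genes changed by 1 on the log2 scale, 60% were recovered in the ES cells, 73.7% at day 2, 82.8% at day 5 against untreated, 81% at day 5 against day 2, 69.4% with siRNA and 0% in the cortex. For a change of 2 the shares were 84%, 92.9%, 94.9%, 95%, 90% and 12.2%. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.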

Results

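RNA was sequenced in 3 mouse systems to ask how the chromatin protein Phf21b affects gene expression, in particular of cell cycle genes, during neuronal differentiation. The first was an A2lox embryonic stem (ES) cell line, kept undifferentiated, that carries an HA-tagged mouse Phf21b under a doxycycline-inducible promoter. It gave 5 libraries labelled mDox and 5 labelled pDox, which per the protocol received 500 ng/ml doxycycline for 24 hours. The second was Neuro2a (N2a), a mouse neuroblastoma line that extends neurites in response to retinoic acid. It gave 2 untreated libraries, 2 libraries at day 2 and 3 at day 5 of differentiation with 20 µM retinoic acid, and 2 at day 2 with siRNA. The third was the embryonic cortex, in which cells were electroporated in utero at E13.5 with a short hairpin RNA against Phf21b (shPhf21b, 3 libraries) or with the control shNTC (3 libraries), and were sorted 4 days later, at E17.5. Depth was 19050639 to 27408626 reads per library in the ES cells, 15029553 to 20173036 in N2a cells and 321826 to 1389034 in the cortex. Levels are deposited normalised read counts (mean ± SD), and fold changes are on the log2(value + 1) scale, with the standard error from limma.

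In the ES cells the induced gene itself did not differ by label. Phf21b was at 123 ± 22.4 in the libraries labelled pDox and 125 ± 22.9 in those labelled mDox (n = 5 each), higher in 2 of the 5 pairs, with a log2 fold change of -0.02 ± 0.18. Its 95% interval within pairs ran from -0.21 to 0.165. The gene that did differ was Hprt, which encodes a purine salvage enzyme and whose locus is the landing site of inducible transgenes in A2lox lines. Hprt was 2.08 ± 0.18 higher on the log2 scale in the libraries labelled pDox (2200.5 ± 464 against 516.5 ± 89.7; adjusted p = 0.0035), and higher in all 5 pairs by 1.88 to 2.23. Phf21a, the paralog of Phf21b, was at 1310 ± 295 and 1326 ± 279. The direction of every ES cell comparison rests on the labels, since Phf21b did not separate them. The series' design text names depletion of Phf21b for its RNA profiles, ES cells included, whereas the labels describe induction, so the sources disagree on what was done to Phf21b in these cells.

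Hprt was the only 1 of 14060 genes called by limma over all 10 libraries, where 35 genes had an unadjusted p under 0.05. edgeR and DESeq2 also called 1 gene each. With the pairs as a block, 68 genes were called, 41 higher and 27 lower in the libraries labelled pDox. Among the lower genes, Ldha, a subunit of lactate dehydrogenase, was at 28953 ± 1693 against 36642 ± 3269 (log2 -0.34 ± 0.04, adjusted p = 7.4e-04). Slc16a3, a lactate exporter, differed by -0.39 ± 0.05 (adjusted p = 0.0042) and Ankrd37 by -0.66 ± 0.11 (adjusted p = 0.023). Lef1, a transcription factor of the Wnt pathway, differed by -0.48 ± 0.08 (adjusted p = 0.013) and Dnmt3l, a cofactor of DNA methylation, by -0.22 ± 0.04 (adjusted p = 0.024). The higher genes included Slc22a23 (0.36 ± 0.06, adjusted p = 0.015), Gpr124 (0.37 ± 0.07, adjusted p = 0.025) and Rab11fip2 (0.40 ± 0.08, adjusted p = 0.032). The within-pair count rested on single pairs: it was 1840 without pair 1, 98 without pair 2, 6 without pair 3, 3 without pair 4 and 6 without pair 5.

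Of 26 gene lists tested in the ES cells, 2 passed over all libraries, both with small shifts. The G1/S and DNA replication list was lower in the libraries labelled pDox, with 41 of 47 members below 0 and a median of -0.04 (adjusted p = 3.1e-04; adjusted p = 0.80 with an estimated correlation). The ATF4 and integrated stress response list, made of genes that answer amino acid shortage, was higher, with 21 of 27 members above 0 and a median of 0.05 (adjusted p = 0.011; adjusted p = 0.80 with an estimated correlation). Single members did not pass the test over all genes, and adjusted over the list alone 0 passed by limma as well. The G1/S call was lost without mDox 5 (adjusted p = 0.50) and without pDox 2 (0.15). The ATF4 call was lost without mDox 1, 2 or 5 and without pDox 1, 3 or 4 (adjusted p from 0.070 to 0.58). Each of these fits ignored the pairing and kept the same-numbered partner of the library left out. Against replicates 3 to 5, replicates 1 and 2 lay at a median log2 difference of -0.19 in both lists (46 and 26 genes). Unequal replicates may therefore account for a lost call, which was not tested. Within pairs 7 lists passed. These 2 did (adjusted p = 3.2e-05 and 0.013; adjusted p = 0.52 and 0.27 with an estimated correlation). The 2-cell-like list was lower with 15 of 16 members below 0 (median -0.21, adjusted p = 3.2e-05), and so were the immediate early list with 16 of 18 members below 0 (adjusted p = 1.8e-04), the mesoderm and endoderm list with 15 of 22 (adjusted p = 0.014) and the cholesterol biosynthesis list with 18 of 24 (adjusted p = 0.037). For these 4 lists the adjusted p was 0.27, 0.26, 0.27 and 0.70 with an estimated correlation. Among the immediate early genes Ier3 was lower by -0.33 ± 0.06 (adjusted p = 0.034). The fibroblast list was higher with 14 of 14 members above 0 (median 0.17, adjusted p = 0.0031; adjusted p = 0.27 with an estimated correlation), and its single members did not pass over all genes, while 4 were higher adjusted over the list alone.

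**Figure D1:**
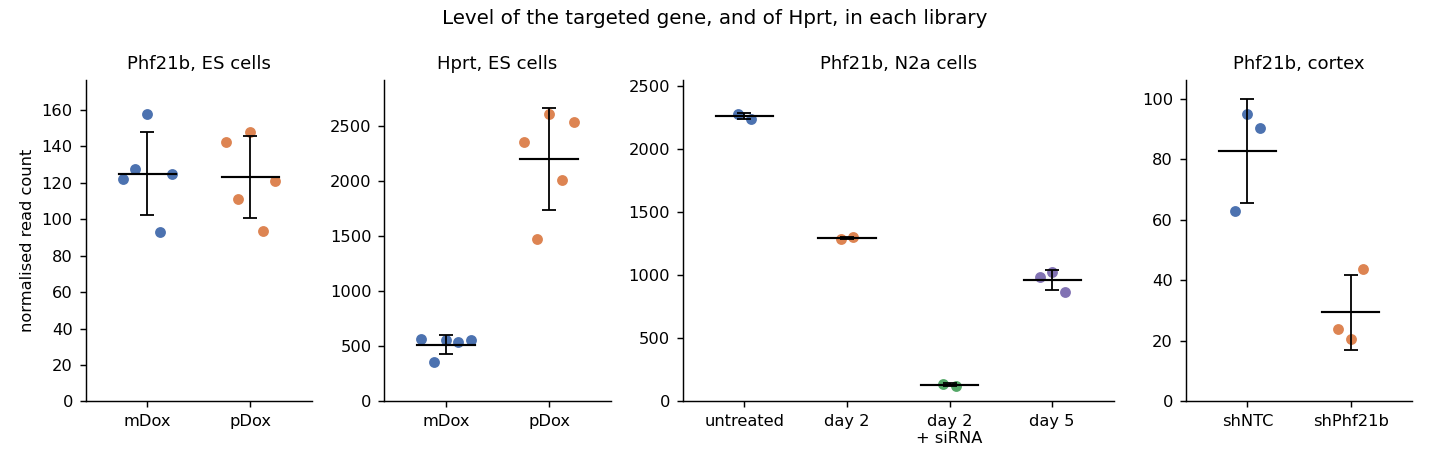
Phf21b in the 3 systems, and Hprt in the ES cells, as deposited normalised read count (vertical axis) in each library (points), with group means and SDs. For Phf21b, libraries labelled pDox and mDox overlapped around 123 and 125, while Hprt was at 2200.5 and 516.5. Mean Phf21b in N2a cells was 2256 untreated, 1296 at day 2, 132 at day 2 with siRNA and 962 at day 5. The 3 shPhf21b libraries (29.5 on average) lay below the 3 shNTC libraries (82.8) in Phf21b.

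After 2 days of retinoic acid, N2a cells had less mRNA of the cell cycle machinery and more of interferon-response genes. The labels do not say whether these day 2 cells also received a control siRNA, so an effect of retinoic acid alone cannot be told apart. Phf21b fell by 0.80 ± 0.11 on the log2 scale, from 2256 ± 24.5 to 1296 ± 9.26 (n = 2 each, adjusted p = 2.2e-04), while Phf21a rose by 0.56 ± 0.12 (973 to 1441, adjusted p = 0.0041). All 46 tested members of the G1/S and DNA replication list and all 46 of the G2/M and mitosis list fell, both over all genes and adjusted over the list alone. Among them were Tyms, thymidylate synthase (1342 ± 38.1 to 169 ± 6.78; log2 -2.98 ± 0.10, adjusted p = 4.1e-07), Pcna, the replication clamp (4636 to 1057; -2.13 ± 0.10), the licensing factor Cdc6 (-3.51 ± 0.28, adjusted p = 1.4e-05) and Mybl2 (-3.25 ± 0.27, adjusted p = 1.8e-05).

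In all, 6082 of 12455 genes changed at day 2, 3038 up and 3044 down, and 1807 of them by at least 1 on the log2 scale. Of 14 retinoic acid response genes 6 rose and 2 fell, and the list did not pass (adjusted p = 0.27). Cyp26b1, which degrades retinoic acid, rose from 189 ± 13.4 to 2986 ± 60.7 (3.97 ± 0.36, adjusted p = 2.6e-05). Tgm2 rose by 0.91 ± 0.12 and the nuclear receptor cofactor Nrip1 by 1.06 ± 0.11, while the binding protein Crabp1 fell by 2.81 ± 0.36. The secreted protein gene Lcn2 was at 197 ± 24.2 against 2.45 untreated. Htr3a, a subunit of the serotonin-gated channel, fell by 3.98 ± 0.25, from 2939 to 185. Of the interferon-response list 16 of 20 members rose, among them Rsad2 (35.6 ± 1.22 to 599 ± 7.20; 4.03 ± 0.37), Oasl2 (2.94 ± 0.26) and the chemokine gene Cxcl10 (72.6 to 422). Of the cholesterol biosynthesis list 16 of 23 members fell (17 adjusted over the list alone), such as Nsdhl (-1.61 ± 0.12) and Idi1 (-1.71 ± 0.17). Neuronal genes went both ways: of 32 pan-neuronal genes 8 rose, for example Crmp1 (0.65 ± 0.09), and 6 fell, for example the neurofilament gene Nefh (-1.84 ± 0.13). Ache, acetylcholinesterase, rose by 2.22 ± 0.20, and the antiproliferative gene Btg2 rose by 1.79 ± 0.16, while the cyclin-dependent kinase inhibitor Cdkn1a fell by 0.89 ± 0.10.

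As groups, G1/S (adjusted p = 2.3e-22, median -1.92), G2/M (1.6e-17, median -1.74), interferon response (3.1e-06, median 1.73) and cholesterol biosynthesis (3.1e-06, median -0.66) passed at day 2. With an estimated correlation the adjusted p was 0.68, 0.68, 0.27 and 0.68. The pan-neuronal list did not pass (adjusted p = 0.86). Without the untreated library 1 the number of changed genes was 4033.

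By day 5 the mitotic genes were lower still, sterol synthesis genes had fallen, and most genes of the catecholaminergic and cholinergic list were lower. The day 5 libraries form a group of their own. A difference between libraries, as seen in Eno1 and Malat1 also among undifferentiated ES replicates, cannot be told apart from differentiation here. Phf21b was at 962 ± 82.0 (n = 3), a log2 change of -1.23 ± 0.10 from untreated (adjusted p = 2.3e-06), and Phf21a was 0.62 ± 0.11 higher (adjusted p = 7.0e-04). All 46 G2/M genes fell, as in the mitotic cyclin Ccnb2 (1628 ± 75.2 to 46.8 ± 9.02; -5.11 ± 0.15, adjusted p = 1.3e-08), and so did 45 of 46 G1/S genes, as in the ribonucleotide reductase subunit Rrm1 (-2.52 ± 0.14). Of the cholesterol list 22 of 23 fell, with Fdps from 5238 to 974 (-2.43 ± 0.09) and Nsdhl by -3.01 ± 0.11. Of 14 catecholaminergic and cholinergic genes 10 fell (11 adjusted over the list alone) and 2 rose. The receptor tyrosine kinase gene Ret went from 20597 ± 553 to 757 ± 279 (-4.83 ± 0.24, adjusted p = 1.4e-07).

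Changed genes at day 5 numbered 8714 of 12455, 4252 up and 4462 down, and 3510 by at least 1 on the log2 scale. The day 5 libraries also stood apart in 2 nuclear RNAs chosen after their values were seen: Malat1 was at 9704 to 17469 against 619 to 2619 in the other N2a libraries, and Xist at 15862 to 37856 against 5061 to 8052. Day 5 library 2 differed more from libraries 1 and 3 (chi-square per degree of freedom 36.7 and 42.5) than these from each other (9.93), where the other N2a groups had 2.04 to 3.18. The largest falls included Dkk1, a Wnt antagonist (6876 ± 285 to 49.7 ± 14.6; -7.13 ± 0.22), Dlk1, which went from 472 ± 9.45 to being listed at 0, and Npy, which went from 305 ± 8.81 to 0.933. Among the largest rises were Lcn2 (2.45 to 1787 ± 534), the matrix gene Ltbp2 (20.4 ± 4.38 to 2735 ± 1724) and Hrk, a pro-apoptotic BCL2-family gene (3.82 to 522 ± 31.3). Eno1, enolase 1, was at 1.48 untreated and 534 ± 81.1 at day 5; it has near-identical processed copies, so its value is uncertain. Of 17 radial glia and progenitor genes 11 fell, such as Sox9 (926 to 153; -2.60 ± 0.13), and 2 rose. Of 32 pan-neuronal genes 18 fell and 6 rose: Syt4, a synaptotagmin, rose from 2455 ± 168 to 10839 ± 898, and Tubb3, neuronal beta-tubulin, fell from 17078 ± 384 to 3640.1 ± 736. Stress genes were among the rises, with the transcription factors Atf3 (373 ± 25.2 to 7156 ± 1384; 4.24 ± 0.15) and Ddit3 (2.57 ± 0.17) and the cystine transporter Slc7a11 (2.97 ± 0.12), although the ATF4 list as a whole had 10 genes up and 8 down of 26 (adjusted p = 0.58).

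The lists that passed at day 5 were G2/M (adjusted p = 5.2e-17, median -3.10), G1/S (3.2e-13, median -1.70), cholesterol biosynthesis (1.3e-09, median -1.89), catecholaminergic and cholinergic neurons (0.0016, median -1.79) and radial glia (0.0035, median -1.22). With an estimated correlation the adjusted p was 0.27 for the catecholaminergic list and 0.52 for the other 4. The pan-neuronal list (adjusted p = 0.076) and the interferon list, with 12 of 20 genes up and 3 down (adjusted p = 0.082), did not pass.

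Between day 2 and day 5 the mitotic and sterol genes fell further, while replication genes went both ways. Here too, a difference of the day 5 libraries cannot be told apart from differentiation. Phf21b fell by 0.43 ± 0.10 (adjusted p = 0.0032), and Phf21a differed by 0.06 ± 0.11 (adjusted p = 0.68). Of 46 G2/M genes 42 fell, 43 adjusted over the list alone, among them Ube2c (1364 to 117; -3.60 ± 0.24). In contrast 16 of 46 G1/S genes rose and 5 fell: the helicase subunits Mcm4 (1.26 ± 0.18, adjusted p = 1.7e-04) and Mcm2 (0.76 ± 0.10) rose, and Dbf4 fell by 0.84 ± 0.11. Of the sterol genes 20 of 23 fell, such as Fdft1 (-2.04 ± 0.09), and of the catecholaminergic genes 10 of 14 fell, with Ret at -4.76 ± 0.24 and Th, tyrosine hydroxylase, going from 186 to 3.40. The cell cycle inhibitors Cdkn1b (-1.19 ± 0.07) and Rb1 (-1.34 ± 0.10) were among 10 of 15 inhibitor genes that fell, while 2 rose. Among retinoic acid response genes 10 of 14 fell, such as the retinol transporter Stra6 (-3.78 ± 0.28), and 3 rose, such as Nrip1 (1.41 ± 0.10). In all 7577 genes changed, 3631 up and 3946 down.

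From day 2 to day 5, 9 of the 23 lists tested passed: G2/M (adjusted p = 2.5e-09, median -1.47), cholesterol biosynthesis (2.2e-07), catecholaminergic and cholinergic neurons (0.0023), inhibitors (0.018), radial glia (0.018; 10 of 17 fell, 3 rose), pan-neuronal (0.018; 18 of 32 fell, 5 rose, with Tubb3 at -2.26 ± 0.14), intermediate progenitors (0.025; 7 of 11 fell, 1 rose), retinoic acid response (0.025) and the ATF4 list, which was higher (0.025; 12 of 26 rose, 10 adjusted over the list alone, and 3 fell). Over these lists the adjusted p ranged from 0.28 to 0.58 with an estimated correlation. The ATF4 call was lost without the day 5 library 3 (adjusted p = 0.069). The G1/S list did not pass (adjusted p = 0.23).

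With siRNA during the 2 days of differentiation, cell cycle genes were higher and neuronal genes lower than at day 2 without it. Phf21b was at 132 ± 11.2 against 1296 ± 9.26 (n = 2 each), a log2 change of -3.28 ± 0.11 (adjusted p = 3.9e-07), and Phf21a also fell, by 0.77 ± 0.12 (1441 to 843, adjusted p = 0.0027). The labels do not say whether the day 2 cells without this siRNA received a control siRNA. Of 46 G1/S genes 42 were higher with siRNA (43 adjusted over the list alone), such as Tyms (169 to 485; 1.52 ± 0.10, adjusted p = 9.8e-05), Fen1 (367 to 1119; 1.61 ± 0.16) and Pcna (1057 to 2087; 0.98 ± 0.10). Of 46 G2/M genes 40 were higher (46 adjusted over the list alone), such as Ccnb2 (534 to 1611; 1.59 ± 0.17, adjusted p = 4.5e-04) and the mitotic kinase gene Aurka (478 to 1436; 1.59 ± 0.19). Of 32 pan-neuronal genes 17 were lower (18 adjusted over the list alone) and 1 higher. Gap43, a growth cone protein, fell from 3406 to 1393 (-1.29 ± 0.13, adjusted p = 3.8e-04), the neuronal RNA-binding protein gene Elavl3 by -1.03 ± 0.10 and the synapsin gene Syn1 by -0.77 ± 0.10.

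With siRNA 2544 of 12455 genes changed, 1239 up and 1305 down, 534 of them by at least 1 on the log2 scale. The largest rises included Myl9, a myosin light chain (39.4 ± 6.36 to 334 ± 9.51; 3.06 ± 0.37, adjusted p = 8.1e-04), Tk1, thymidine kinase (294 ± 20.6 to 1549 ± 137; 2.39 ± 0.27) and Htr3a (185 to 756; 2.02 ± 0.25). The largest falls included Gas6, a ligand of receptor tyrosine kinases (67.3 to 10.8; -2.53 ± 0.29), Dnm3 (152 to 27.1; -2.45 ± 0.25) and Adap1 (199 to 38.5; -2.35 ± 0.17). Of 16 immediate early genes 8 fell (12 adjusted over the list alone), among them Atf3 (901 to 380; -1.25 ± 0.16) and Junb (-0.72 ± 0.10). Of 23 cholesterol genes 8 rose (11 adjusted over the list alone), such as Tm7sf2 (1.03 ± 0.18, adjusted p = 0.0042). The DNA methyltransferase gene Dnmt3a fell by 1.32 ± 0.07 (adjusted p = 4.7e-05), and Hdac1, a subunit of the LSD1-CoREST complex, rose by 0.77 ± 0.10 (adjusted p = 0.0011). Of 20 interferon-response genes 3 rose and 1 fell.

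The lists that passed with siRNA were G1/S (adjusted p = 7.7e-27, median 1.10), G2/M (9.7e-22, median 1.19), pan-neuronal (1.4e-06, median -0.39), immediate early (1.2e-05, median -0.65) and cholesterol biosynthesis (1.2e-05, median 0.32). Their adjusted p was 0.48, 0.66, 0.34, 0.34 and 0.71 with an estimated correlation. The rotation test did not call the cholesterol list (adjusted p = 0.064). With 1 library fewer, fewer genes passed: 752 without day 2 library 1, 855 without day 2 library 2, 689 without siRNA library 1 and 978 without siRNA library 2. These 5 lists passed in each of these 4 fits. With only the day 2 groups with and without siRNA in the fit, 6407 genes passed.

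Against the untreated cells, the cells differentiated with siRNA still had lower replication genes. There 31 of 46 G1/S genes were lower and 0 higher by limma (median -0.72), 17 of 46 G2/M genes were lower (median -0.59), and 16 of 20 interferon-response genes were higher (median 1.84), while 4702 genes changed in all. Of the 6082 genes changed at day 2, 4929 (81.0%, 95% interval 80.0 to 82.0) had the opposite sign with siRNA. Among all tested members of a list, called or not, the sign was opposite for 46 of 46 G1/S, 46 of 46 G2/M and 23 of 23 cholesterol genes. It was opposite for 8 of 20 interferon-response, 8 of 19 Notch pathway and 2 of 10 naive pluripotency genes. Other lists lay between, such as pan-neuronal (22 of 32), ATF4 (18 of 26), immediate early (12 of 16) and catecholaminergic genes (11 of 14). Differences between lists were not tested. Both comparisons use the day 2 libraries, and in simulated draws without any effect the share was 76.1% (74.7 to 77.3 over 100 draws) among the 6082 genes with the largest day 2 statistic. All draws used here held no change at day 2 either, so their top genes were picked on noise in the shared libraries. They do not give the share, or the correlation, for real day 2 changes without an siRNA effect. Over all 12455 genes the share was 70.5%, against a simulated 66.7% (65.5 to 67.7). The correlation of the fold changes over genes was -0.588 against a simulated -0.502, and the covariance was -0.218 against -0.0222, a difference of -0.195. Genes up at day 2 and down with siRNA numbered 793 (318 for independent lists), those down and then up 919 (303), those up in both 49 (302) and those down in both 67 (319). The day 2 group has 2 libraries and was not split, so part of the excess may come from the shared libraries. In the comparison of day 5 with untreated, which shares no library with the siRNA comparison and was added after the data were seen, 5969 of 8714 genes (68.5%, 67.5 to 69.5) had the opposite sign. The correlation over all genes was -0.403 there and the covariance -0.236. Genes are not independent replicates in these shares.

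**Figure D2:**
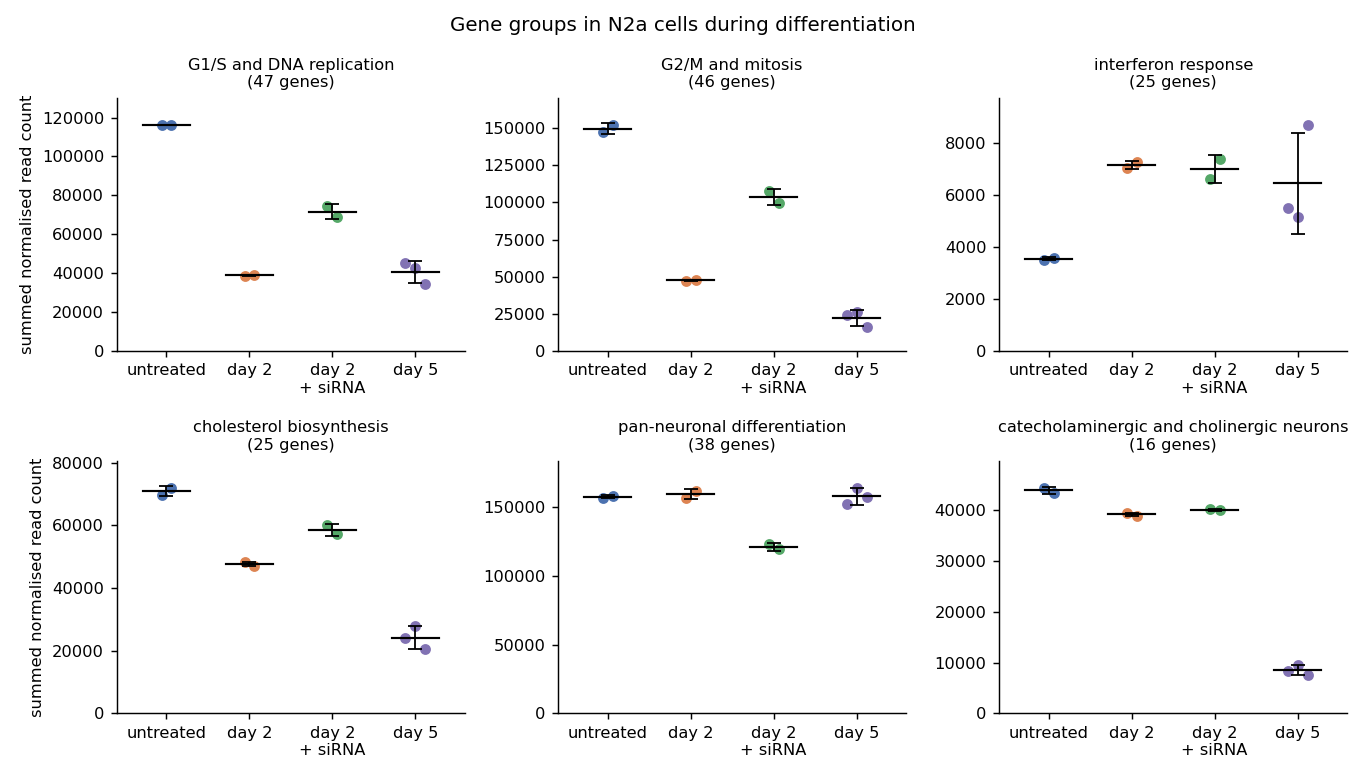
Summed deposited normalised read counts (vertical axis) of the genes of 6 lists in each N2a library (points), by group. The G2/M sum was 147265 to 152262 untreated, 47215 to 47629 at day 2, 99696 to 107670 at day 2 with siRNA and 15794 to 26358 at day 5, and the interferon-response sum was higher in every differentiated library (5164 or more) than untreated (3508 to 3584).

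In the sorted cortical cells Phf21b was lower with its hairpin, and mitotic genes as a group were higher and projection neuron genes lower, but no single gene passed. Phf21b was at 29.5 ± 12.4 against 82.8 ± 17.3 (n = 3 each; 18 to 27 reads against 74 to 165), with a log2 difference of -1.51 ± 0.49 and no overlap of the groups (adjusted p = 0.90). Phf21a differed by 0.02 ± 0.49 (-0.053 with TMM factors). Of 33 tested G2/M genes 29 were above 0 (median 0.71, adjusted p = 4.6e-05; adjusted p = 0.37 with an estimated correlation), with Top2a, topoisomerase 2 alpha, at 171 against 68.3 (1.40 ± 0.39) and Hmgb2 at 0.83 ± 0.35. Of 33 projection neuron genes 24 were below 0 (median -0.55, adjusted p = 4.6e-05; adjusted p = 0.13 with an estimated correlation). Among them were the upper-layer transcription factor gene Cux2 at 63.7 ± 16.7 against 153 ± 29.8 (-1.27 ± 0.37) and Tbr1, a transcription factor of deep-layer neurons, at 117 against 217 (-0.96 ± 0.36).

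The G1/S list did not pass in the cortex (adjusted p = 0.33), with 22 of 34 genes above 0 and a median of 0.39. Its medians per library were 0.68, -0.04 and 0.16 in shPhf21b 1, 2 and 3 and 0.0025 to 0.28 in shNTC. Further lists did pass. Of 26 radial glia genes 18 were above 0 (median 0.31, adjusted p = 0.0499), among them Notch1 (1.45 ± 0.43) and Sox2 (1.65 ± 0.52). Of 34 pan-neuronal genes 22 were below 0 (median -0.14, adjusted p = 0.019), among them Crmp1 (-0.93 ± 0.31), and 8 of 10 LSD1-CoREST genes were below 0 (median -0.42, adjusted p = 0.011), among them the demethylase gene Kdm1a (-0.73 ± 0.35). Of 11 interneuron genes 10 were above 0 (median 1.21, adjusted p = 0.011), among them Dlx1 (1.23 ± 0.58). For each of these 4 lists the adjusted p was 0.37 with an estimated correlation. Of the tested genes, 4 of 11 interneuron, 3 of 26 radial glia and 5 of 33 G2/M genes had an shNTC mean under 10. These reached the filter on low values only through shPhf21b, and 1 interneuron gene only through shNTC. Without the filter, a setting added after the data were seen, 17 of 18 interneuron genes were above 0. So were 20 of 30 radial glia and 38 of 46 G2/M genes. The intermediate progenitor list did not pass (adjusted p = 0.060), with 8 of 11 genes below 0, such as Insm1 (-1.24 ± 0.43).

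Markers of vessels and connective tissue moved with the same label in 2 of its 3 libraries. All 9 tested endothelial and pericyte genes (mean 2.91, adjusted p = 1.5e-04) and all 9 fibroblast and meningeal genes (mean 2.80, adjusted p = 8.5e-05) were above 0, each with an adjusted p of 0.37 with an estimated correlation. All of these genes had a mean under 10 in shNTC and so reached the filter on low values only through shPhf21b, which sets their direction. Without the filter, a setting added after the data were seen, 14 of 16 members of each list were above 0 (adjusted p = 1.3e-05 for each). Col1a2, a collagen gene, was at 195, 155 and 3.36 in shPhf21b 1, 2 and 3 and at 0 to 17.9 in shNTC. The summed endothelial and pericyte values were 307 and 827 in shPhf21b 1 and 2, 20.2 in shPhf21b 3 and 21.8 to 28.2 in shNTC. The summed fibroblast values were 772 and 862, against 21.9 in shPhf21b 3 and 1.28 to 79.4 in shNTC. Interneuron sums followed these libraries (602 and 620 against 138 in shPhf21b 3 and 112 to 278 in shNTC), and so did astrocyte lineage sums (449 and 485 against 139 and 153 to 346). Oligodendrocyte lineage sums were 62.0 to 110 in the 3 shPhf21b libraries against 19.2 to 35.9 in shNTC. The G2/M sums were 1794, 1906 and 2588 in shPhf21b 1, 2 and 3 against 1145 to 1502 in shNTC. Over the genes of that list the median log2 ratio to the shNTC mean was 0.44, 0.11 and 0.91 against -0.09 to 0.35 in shNTC, so shPhf21b 2 lay within the shNTC range. The highest median came from shPhf21b 3, the shallowest cortex library (321826 reads). The projection neuron sums were 6162, 7226 and 8995 against 9180 to 10601. A microglial sum of 672 stood in shNTC 3 (1.28 to 138 elsewhere), and shPhf21b 2 was the only library with Y-linked transcripts.

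By limma 0 of 7910 cortical genes passed, with 350 at an unadjusted p under 0.05 and a smallest adjusted p of 0.90; edgeR called 0 (340 at an unadjusted p under 0.05) and DESeq2 called 2. The groups did not overlap for 842 genes, where chance gives 10% or 791, and 8 genes passed without shPhf21b 3. With libraries like these a log2 change of 1 was recovered for 0% of simulated genes, so changes of that size were not detectable gene by gene. The G2/M and projection neuron calls held without any 1 library. Calls were lost for LSD1-CoREST without shPhf21b 1 (adjusted p = 0.11) or 2 (0.081), for interneurons without shNTC 2 (0.051), shPhf21b 1 (0.40) or 2 (0.065), for pan-neuronal genes without shNTC 3 (0.091) or shPhf21b 3 (0.25), and for radial glia without shNTC 1 (0.34), shNTC 3 (0.073), shPhf21b 1 (0.14) or 3 (0.28), without the filter on low values (0.079) and with a pseudocount of 5 (0.054). The endothelial call was lost without shPhf21b 1 (0.11), fewer than 5 of its genes were left without shPhf21b 2, and the fibroblast call without shPhf21b 1 (0.14) or 2 (0.075). Without shPhf21b 1 and 2 together, a setting added after the data were seen, G2/M (8.0e-06), projection neurons (0.046), radial glia (0.046), pan-neuronal genes (0.016) and cholesterol biosynthesis (0.033, lower) passed, on 1 remaining shPhf21b library. With an estimated correlation the adjusted p was 0.73 for radial glia and 0.49 for the other 4.

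**Figure D3:**
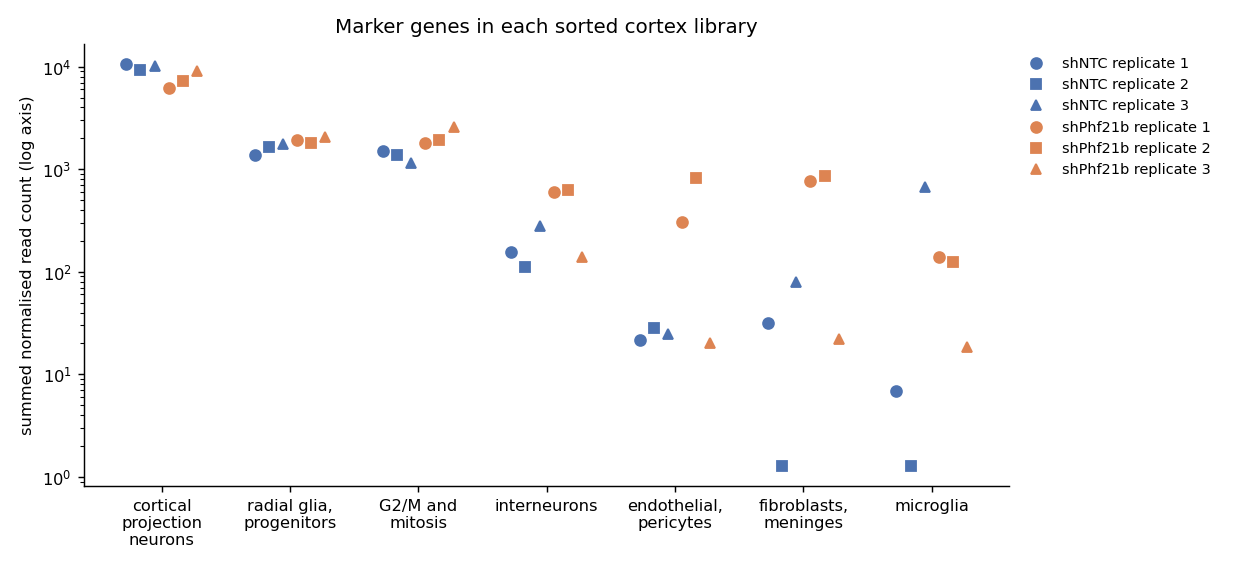
Summed deposited normalised read counts (vertical axis, log scale) of marker lists in each of the 6 cortex libraries (points), by group. The shPhf21b libraries 1 and 2 stood apart in endothelial (307 and 827) and fibroblast transcripts (772 and 862), while all 3 shPhf21b libraries lay above shNTC in summed G2/M transcripts, although not in the median over the genes of that list, which was 0.11 (log2 ratio to the shNTC mean) in shPhf21b 2 and 0.35 in shNTC 1.

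Calls were compared between the systems, whose tables were normalised separately. Only Hprt was higher both in the libraries labelled pDox and with siRNA in N2a cells (1 shared of 1 and 1204 genes over 11728 tested in both, 0.103 expected, Fisher's exact p = 0.103). The other overlaps held 0 genes, because limma called 0 genes lower in the ES cells and 0 in the cortex. Among 1566 genes called with siRNA and tested in the cortex, 906 (57.9%, 95% interval 55.4 to 60.3) had the same sign there, and 57.2% of 1508 genes outside the cell cycle lists. This interval treats genes as independent, which they are not. The cell cycle lists leave out genes such as Tk1, so cell cycle genes may remain among the 1508. The mean signed score of the 1566 genes was 0.20, 0.25 and 0.37 in the shPhf21b libraries and 0.14, -0.04 and -0.10 in shNTC. The difference of 0.275 had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow.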

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

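The tests on Phf21b in the ES cells, on shPhf21b 3 and on the mitotic genes of that library were chosen only after the result was seen, whereas the counts over other splits of the samples were chosen before. The test with second marker lists was set before the values of those lists were seen, but for a pattern already seen in shPhf21b 1 and 2. Of 44 sets, each the values of 1 gene in the 5 libraries of 1 ES cell label, 2 had a library far from the others, where chance gives about 2.2. Hprt was at 357 in mDox 2 and at 544 to 565 in the other libraries labelled mDox. Ankrd37 was at 200.3 in mDox 1, with the nearest other library at 128. The cholesterol biosynthesis list went opposite ways in 2 systems by its mean log2 difference, at -0.30 in the shPhf21b cortex (-0.67 to -0.09, against -0.12 to 0.09 in shNTC) and 0.40 with siRNA in N2a cells (0.36 to 0.43), and this difference was not tested. The list was not called in the cortex, where the highest shPhf21b library lay within the shNTC range. Its siRNA call was lost with an estimated correlation (adjusted p = 0.71) and by the rotation test (0.064). By summed values shPhf21b 2 (813) lay within the shNTC range of 698 to 867.

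Phf21b did not rise in the ES libraries labelled pDox, although the line carries an inducible Phf21b. An absent doxycycline treatment is argued against by Hprt, next to which the cassette is inserted in A2lox lines, at a log2 difference of 2.08 with no overlap of the groups. Too few reads are argued against by the upper end of the within-pair interval at 0.165, far below a doubling. What stays open is an induced transcript that was not counted under Phf21b, for example one counted nowhere or removed as ambiguous, or a line without this cassette: 67 genes besides Hprt differed within pairs, and gene totals alone cannot tell these apart. An effect of Phf21b itself on those genes may therefore be neither assumed nor excluded. An effect of doxycycline itself cannot be told apart either. Per the protocol every library labelled pDox received it, and no treated control cells without the inducible Phf21b were sequenced in the series.

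For the number of ES cell calls, chance could not be excluded by splits that ignore the pairing. The 1 gene called over all libraries, Hprt, was matched or exceeded in 6 of 100 splits, the highest other calling 6118 genes with replicates 1 and 2 of both labels and pDox 4 apart from the rest, which points to a structure of the samples, and the other 12 splits that part all 5 pairs called 0 genes by limma and at most 2 lists, these 13 being too few for a share under 0.05. The 2 lists were matched in 85 of 100 splits (highest other 9). The 68 within-pair genes were matched in 2 of the 16 ways to swap labels within pairs (highest other 649, on swapping pair 1), which are too few ways for a share under 0.05.

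In the cortex, vascular and fibroblast transcripts were high in shPhf21b 1 and 2. Cells of vessels and meninges in these libraries may account for this, although sorting of electroporated cells would remove them: 2 second lists of 19 detected genes each, of which 15 and 17 were also seen in shNTC, had medians of 3.14 and 3.16 in shPhf21b 1 and 3.32 and 2.11 in shPhf21b 2, all above the bound of 1 set beforehand. Abundant transcripts of these cells were higher with them, such as Col4a1 at 168 and 280.3 against 3.36 in shPhf21b 3 and 7.05 to 14.1 in shNTC, a gene chosen after its values were seen. The second lists hold further markers of the same cells, in the libraries where the pattern had been seen, so they are not independent evidence. Their medians would be high under an effect of the knockdown as well. Such an effect stays open, since the median of both lists was -0.20 in shPhf21b 3 and that is 1 library. The higher mitotic genes cannot be told apart from such cells in shPhf21b 1 and 2. In shPhf21b 3, without those transcripts, the G2/M median was 0.91 against at most 0.35 in shNTC. It was 0.44 in shPhf21b 1 and 0.11, within the shNTC range, in shPhf21b 2. The value of shPhf21b 3 comes from 1 library, the shallowest in the cortex at 321826 reads, and a part of depth in it was not tested. The lower projection neuron genes cannot be told apart from such cells in shPhf21b 1 and 2 either. Their median log2 ratios were -0.54, -0.53 and -0.21 in shPhf21b 1, 2 and 3, against 0.02 to 0.07 in shNTC. By mean ratio shPhf21b 3 was lowest, at -0.60 against -0.34 and -0.33.

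Splits of the 6 cortex libraries number 10, too few for a share under 0.05. The real split gave 0 genes, so all 10 match it by construction and the gene count says nothing about chance (highest other 7). Only 1, the real one, gave 8 lists (highest other 5).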

How the results depend on the processing

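The alternatives that leave out ES cell pairs, that leave out shPhf21b 1 and 2 together, that drop the filter for cortex lists (10 lists passed) and that use the day 5 comparison without shared libraries were chosen only after the result was seen. Over the pseudocounts, scalings, block and libraries left out, the genes followed for the text kept direction and side of the threshold in 1957 cases, lost the call in 14, gained it in 12 and changed sign in 12, all 12 for Phf21a where it was not called. Phf21b, counted apart from these, changed sign in the ES cells only, where it was not called either. List calls were kept in 279 cases, lost in 72 and reversed in 1.

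With the pairs as a block the ES cells gave 68 genes and 7 lists, and leaving out 1 pair 3 to 1840 genes. In N2a cells and the cortex libraries share only a number (correlations -0.0746 to 0.0444 and -0.15 to -0.025), and a block gave 6390, 8660, 7431, 2859 and 0 genes in the order of the report. It ended the calls of the ATF4 list from day 2 to day 5 (adjusted p = 0.069) and of cortical radial glia (0.057), and brought in the interferon list at day 5 (0.025) and the G1/S list from day 2 to day 5 (0.0035); it changed no other list call there. Of 489 gene entries covered by the naming rule there, it ended the call of 4 and brought in 5.

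With an estimated correlation 0 lists passed in all 6 comparisons, against 2, 4, 5, 9, 5 and 8 by camera. The rotation test gave 0 in the ES cells and the cortex and 9, 18 and 20 in the differentiation comparisons. It does not compare a list with other genes.

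A minimum log2 change of 1 left 1807, 3510, 2496 and 534 genes in N2a cells. With only the 2 groups compared in the fit, 6407 genes passed with siRNA. In the shared fit the spread of the day 5 libraries enters every p-value. Their chi-square per degree of freedom was 9.93 to 42.5, against 2.04 to 3.18 in the other N2a groups. The part of this in the lower count was not tested. DESeq2 called 2 genes in the cortex. Among genes also changed the same way at day 5 the opposite-sign share with siRNA was 84.4% (67.3% in simulated draws without any effect, as the day 2 libraries are shared), and over day 5 changes 68.5%. Those draws held no effect of differentiation either, so the share for real day 2 changes without an siRNA effect was not simulated.

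Without 1 library in turn, fewer samples gave 4033 to 4181 genes at day 2, 7127 to 9521 at day 5, 5686 to 8760 between them, 689 to 978 with siRNA and 0 to 8 in the cortex, and 1 to 6 lists in the ES cells and 3 to 8 in the cortex. Counts moved by over 1.5 times without untreated 1 (4033), without each day 2 library (752, 855) and each siRNA library (689, 978), without shPhf21b 3 (8 genes), and for lists without mDox 4 (4), mDox 5 (1), pDox 5 (6), shPhf21b 1 (3) and shPhf21b 2 (4). In the ES cells the partner of the library left out stayed in, so the labels then held unequal replicates. Phf21b in the ES cells ranged from -0.12 to 0.073, and Phf21a from -0.14 to 0.082 there, -0.052 to 0.13 from day 2 to day 5 and -0.44 to 0.59 in the cortex, where TMM factors gave -0.053 and recomputed median ratios -0.0030. Without shPhf21b 1 and 2, 5 lists passed, and the interneuron list reversed (adjusted p = 0.81; 9.4e-04 to 0.40 without 1 library). Other scalings moved the median of all genes by at most 0.07. In the cortex 12.2% of simulated changes of 2 were recovered; depth, library number and spread between libraries were not varied separately.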

Other observations

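All tests in this part were chosen only after the result was seen, apart from the share of siRNA genes with the same sign in the cortex, and the genes Tpi1, Pgk1, Hmox1, Srxn1, Osgin1, Prdx1, Tkt, Fth1, Malat1, Eid3, Gm13253 and Gm5177 were chosen after their values were seen. In the ES cell pairs, genes of glycolysis and of the response to low oxygen lay lower in the libraries labelled pDox. Of 35 members of such a list 9 were called within pairs, all lower, among them Ldha (-0.34 ± 0.04), Tpi1 (-0.27 ± 0.04, adjusted p = 0.0084) and Pgk1 (-0.27 ± 0.05, adjusted p = 0.020). Of the 26 other members 21 (80.8%) were below 0, against 48.3% of all genes, which is in line with a lower glycolysis programme. The median of the list was -0.46 in pair 1 and -0.09 to -0.14 in the other pairs, so the size rests largely on pair 1. Differences in oxygen or density of the paired cultures may produce the same values and were not tested. An effect of doxycycline itself cannot be told apart from the label.

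At day 5 in N2a cells, genes known as targets of the oxidative stress factor NRF2 were among the rises: Hmox1, heme oxygenase 1, went from 1752 to 12991 (2.89 ± 0.07, adjusted p = 7.3e-09), Srxn1, sulfiredoxin, rose by 3.88 ± 0.11 and the cystine transporter gene Slc7a11 by 2.97 ± 0.12. A general NRF2 response is argued against, since of 17 other list members 4 (23.5%) rose, among them Osgin1 (2.96 ± 0.30) and Fth1 (0.99 ± 0.11), and 6 fell, among them Prdx1 (-1.48 ± 0.21) and Tkt (-1.07 ± 0.09), while 34.1% of all genes rose.

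Eno1 was at 440.0 to 581 in the 3 day 5 libraries and at 0 to 3.48 in the other 6 N2a libraries. Induction by differentiation is argued against as the whole cause, because in undifferentiated ES cells Eno1 was at 1733 to 1874 in replicates 1 and 2 and at 0.82 to 7.63 in replicates 3 to 5, with a log2 ratio of at least 8.56 in both labels. Eno1, Eid3, Gm13253 and Gm5177, 4 genes, were on or off in both of these sets of libraries, from 24 and 6 such genes. By independence 0.0123 shared would be expected (Fisher's exact p = 2.0e-10). Without Eno1, which prompted the test, 3 were shared from 23 and 5 (Fisher's exact p = 6.6e-08). This overlap points to a difference between libraries that both sets share, and not to its cause. A candidate explanation is that reads at genes with near-identical copies were counted differently between libraries. Whether all 4 genes have such copies was not tested, and another difference between libraries could give the same overlap. Whether the same difference lies behind other day 5 changes cannot be told apart from differentiation, since the day 5 libraries form a group of their own and the correlation over genes with the ES replicate difference was 0.23. Among 8217 genes with an ES replicate difference under 0.5, 5608 (68.2%) still changed at day 5, and all 37 tested G2/M genes among them fell.

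Malat1, high at day 5 in N2a cells, was at 16353 to 20757 in ES replicates 1 and 2 against 1690 to 4517 in replicates 3 to 5. An effect of Phf21b knockdown shared by N2a cells and cortex was set beforehand at over 60% of siRNA genes with the same sign in the cortex, and the share of 57.9% fell between that bound and the 50% that would have argued against it.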
